A study of Gallus gallus with 2 samples.

How the data were processed

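Total RNA of 2 DT40 cultures, each with both H2A.Z genes knocked out and a FLAG-tagged H2A.Z.1 or H2A.Z-R80C transgene, was labelled with Cy3 and hybridised to 1-colour Agilent chicken expression arrays, per the labels' protocols. There was 1 array per group. Both arrays lay on 1 slide and came from 1 scan, per the file headers. Samples were grouped by the stably expressed protein named in the labels.

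The deposited scanner files hold spot intensity on a linear scale, made with Agilent Feature Extraction 11.5.1.1 under protocol GE1_1105_Oct12, per the file headers. The processed intensity is background-subtracted and detrended within an array, and was not normalized between arrays. The files also hold raw median spot and background intensity, and 0 or 1 flags per spot (well above background, positive and significant, saturated, outlier), per the file headers. The series matrix deposited by the authors holds linear intensity as well, and its basis is not stated. Set against the scanner files, each column was the processed signal times a near-constant factor, 1.50 for the H2A.Z.1 array and 1.51 for the R80C array, neither log-transformed nor centred, with column medians of 129.9 and 125.1. How the factor was chosen stays unknown. All of its sample columns were matched to a sample.

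The main values were log2 of the processed signal minus the log2 of the array's 75th percentile over non-control spots (1078 and 1055). Spots of a probe were averaged. A probe counted as measured where it was well above background on both arrays, with no saturated or outlier-flagged spot (1 spot was outlier-flagged on the H2A.Z.1 array and 0 on the R80C array). Of 43603 probes, 30200 (69.3%) were measured on both arrays. The lowest signal well above background was 6.95 and 5.81, and the median local background 30 and 28.5. A gene's value was the mean of its measured probes, and all differences are R80C minus H2A.Z.1. Where all probes of a gene were below that flag on 1 array and at least 1 was above it on the other, the difference is a lower bound: the bright value minus the higher of the dim probe's own value and the lowest value well above background on that array. Where several probes were above the flag, the largest of their bounds was kept. Each bound thus belongs to 1 probe and is not a mean over the gene. The R80C minus H2A.Z.1 differences of the probes of 1 gene lay 2-fold or more apart in 3 of the 2776 genes with several measured probes (YPEL2, ETV1 and COL1A2). This does not describe how far the signals of such probes differ.

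The files carry accessions and no gene symbols. Of 13060 probes with a RefSeq accession, 11935 matched an accession, without its version, in a RefSeq table of assembly GRCg7b, which gave 5382 named genes, and 1125 did not match. A further 14692 probes carried an Ensembl transcript and 15851 another accession, and these were left unnamed. The arrays' grid is of build galGal3, per the file headers, so the table served for names and the order of neighbouring genes only. Symbols are those of the table, and some are old or unofficial.

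With 1 array per group, no test, p-value or standard error was computed, and the number of arrays limits the precision. Counts of genes use a threshold of 2-fold. The spread between repeated spots, between probes of a gene and between 8 Agilent spike-in probes (mean difference 0.020, range -0.029 to 0.071) describes technical error only. Before the data were examined, 28 gene lists were written down, of which 27 had at least 5 measured genes, with 539 measured genes in all. List members were matched by symbol or, for 23 measured members, by a synonym in the table, which in some cases points to a related gene. The median of each list was placed among the medians of 10000 random lists of the same size, drawn from 10 signal classes to match its members' mean signal. A list stood apart below percentile 1 or above percentile 99. This describes the 2 arrays and is no test between genotypes.

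The rule for named genes was fixed before the data were examined. It took named genes measured on both arrays, whose brighter array reached the median signal of measured genes and whose probes all differed in the same direction, and named the 12 with the largest positive and the 12 with the largest negative difference. It added the 4 genes per direction with the largest lower bound among genes measured on 1 array, the H2A.Z genes, and in each list the 2 members farthest from 0 in the direction of its median plus any member at least 2-fold different. Under this rule HBBA alone is named for the erythroid list, because the other member came from a synonym that points to a related gene. Genes at least 2-fold different that fell outside the rule were named after their values were seen.

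The alternatives were the array median, quantile normalization, loess between the arrays, normexp (offset 50) with quantile normalization, the series matrix values, scaling on the spike-in probes, no filter on dim probes, only genes at or above the median signal, outlier flags ignored, and the median or the brightest probe of a gene. For genes measured on 1 array, the lenient flag (positive and significant) replaced the strict one in deciding which probes were present. The bound still used the lowest value well above background under the strict flag. Normexp had been planned on the mean spot signal, which the files do not hold, and was run on the median spot signal. Matching list members by exact symbol only was added after seeing the data. The procedure was tested on simulated data for the 4326 genes of this comparison, with the spread between probes as noise. It called 100% of 50 genes each made 2.5-fold higher, 4-fold higher and 2.5-fold lower, 0% of 50 made 1.5-fold higher, and 0 of 4126 unchanged genes. The noise had 1 SD of 0.097 (log2) for all genes, below the SD of 0.13 between probes in the dimmer part. The simulation kept the real detection flags and held no variation between cultures. These rates therefore check the procedure and give no rate of false calls for the real arrays. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and in R 4.3.3 with limma 3.58.1.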

Results

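Gene expression was measured in DT40 cells, a chicken B cell line, in which both H2A.Z genes had been knocked out. H2A.Z is a histone variant that replaces H2A in part of the nucleosomes. The cells stably expressed a FLAG-tagged protein that was either H2A.Z.1 or the mutant H2A.Z-R80C, and both cultures were grown without tetracycline. The design held 2 groups with 1 array each, hybridised on the same slide and read in the same scan, so that slide and scan did not separate the groups. The comparison addressed how the transcriptome of cells with the cancer-associated mutant differed from that of cells with H2A.Z.1, in a study concerned with nucleosome stability and passage through mitosis. With 1 array per group there was no test, no p-value and no replicate error, and every difference below describes these 2 arrays.

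The arrays were of similar quality. Of 43803 non-control spots, 70.1% lay well above background on the H2A.Z.1 array and 71.5% on the R80C array, and no spot was saturated. The 75th percentile of the processed signal was 1078 and 1055, respectively. Among 40 probes printed 5 times, the difference between the arrays had a standard deviation (SD) of 0.053 (log2) between spots, and among the 2776 named genes with several measured probes it had an SD of 0.097 between probes of 1 gene. These SDs describe technical precision only.

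The H2A.Z genes were examined first. H2AFZ, the gene of H2A.Z.1, was read by 2 probes. The first gave a processed signal of 1537 in H2A.Z.1 cells and 1475 in R80C cells, a log2 difference (R80C minus H2A.Z.1) of -0.028, and the second gave 883 and 933, a difference of 0.11. Their mean was 0.041, and the brighter probe alone carried the opposite sign. No probe was named for the gene of H2A.Z.2. Where the probes lie relative to the disrupted part of the gene and to the transgene is not given in the sources used here, so these signals checked neither the knockout nor the genotype labels.

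The 2 transcriptomes were close to each other. Of 4326 named genes measured on both arrays, 99.5% differed by less than 2-fold and 98.1% by less than 1.5-fold, with a median log2 difference of 0.013 and an SD of 0.20. Signals given for a gene are arithmetic means over its probes, whereas differences and folds are means of log2 values, so the ratio of the signals can differ from the fold where a gene has several probes. Scaled signals were at least 2-fold higher in R80C cells for 7 genes and at least 2-fold lower for 13. THRB, a thyroid hormone receptor, had a difference of 2.16 (log2), the largest in the main setting, with a signal of 20.6 in H2A.Z.1 cells and 90.2 in R80C cells. Its value was 0.87 after normexp background correction with quantile normalization and 0.96 with no filter on dim probes, below OAF, SNCG and SDC4 in both. OAF followed with 1.74, SNCG (gamma-synuclein) with 1.68, SDC4 (syndecan-4, a cell-surface proteoglycan) with 1.53 and MTSS1, which binds actin and membranes, with 1.48. The microtubule-binding protein gene DCX had a difference of 1.06 and RGS7, a regulator of G protein signalling, of 1.01. These were 0.56 and 0.34 after normexp with quantile normalization, and 0.67 and 0.85 with no filter on dim probes. RGS7 also fell just under 2-fold with the series matrix values, spike-in scaling, and the median or brightest probe, and DCX with the brightest probe.

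The largest negative difference in the main setting belonged to LOC395551, at -2.26 (148 in H2A.Z.1 cells and 27.8 in R80C cells), which stood at -1.13 after normexp with quantile normalization, behind MND1 at -1.22. It was followed by MND1, which acts in meiotic recombination, at -1.57 (488 and 161), CD3E, a chain of the T cell receptor complex, at -1.54 (340 and 95.4), and GAS2L3, a linker of actin and microtubules that acts in cytokinesis and was on none of the lists, at -1.47 (199 and 70.3). APP, the amyloid precursor protein gene, was lower by 2.24-fold over 3 probes, SELENOP1, a selenoprotein P gene, by 2.12-fold over 3 probes, and BEND7 by 2.07-fold over 3 probes. HIC2, GATSL2, SLC41A2, CDH2, PRPS2 and SPATA4 had differences between -1.21 and -1.05. Apart from PRPS2 these were dim, from 24.0 in H2A.Z.1 cells and 10.9 in R80C cells for CDH2 to 13.8 and 6.52 for SPATA4. After normexp with quantile normalization the dim ones lay between -0.31 (CDH2) and -0.15 (SPATA4), and PRPS2 at -0.75. All 20 genes lay below the median signal that the rule for named genes required. They were therefore named after their values were seen, apart from CD3E, which the rule also took as a list member at least 2-fold different. Of the 20, 10 had several measured probes, which differed in the same direction in all 10. The other 10, among them THRB, OAF, SDC4, MND1 and GAS2L3, rested on 1 measured probe each. The genes with several probes were picked on the mean of the same probes, so the shared direction is no separate evidence. The counts moved with the processing: after normexp background correction of the raw median signal and quantile normalization 3 genes were higher and 2 lower, and with no filter on dim probes 52 were higher and 45 lower.

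**Figure D1:**
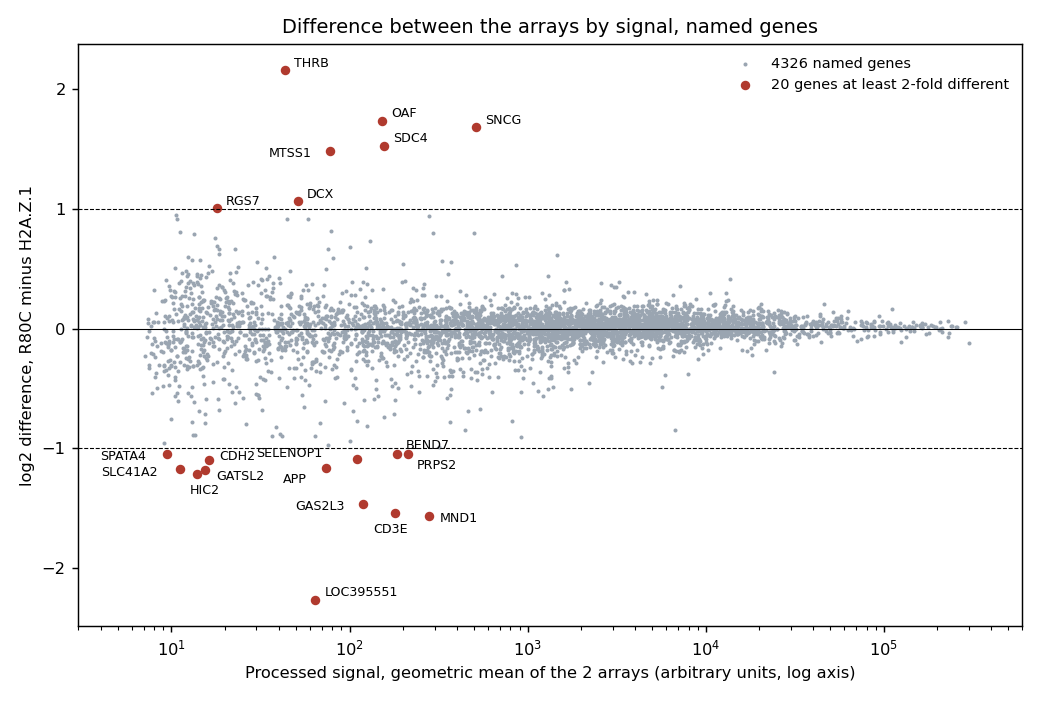
Each point is 1 of the 4326 named genes measured on both arrays, with the geometric mean of its processed signals on the x axis (log scale, arbitrary units) and the log2 difference, R80C minus H2A.Z.1, on the y axis. The dashed lines mark 2-fold, and the 20 genes beyond them, 7 above and 13 below, lie at low and middle signals.

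Among the 2163 genes at or above the median signal, none differed by 2-fold and 2 differed by 1.5-fold. These were CMSS1, with a signal of 9106 in H2A.Z.1 cells and 4961 in R80C cells (-0.85, 1 probe), and SH3GLB2 (-0.77, 1 probe). The next largest negative differences among genes whose probes pointed one way were those of AK1, an adenylate kinase (-0.56), ALDH4A1, a mitochondrial dehydrogenase of proline breakdown (-0.52), the annexin gene ANXA11 (-0.51), and BAK1, a pro-apoptotic BCL2 family member (-0.50, 4 probes). GRAPL stood at -0.49, JCHAIN, whose product joins polymeric immunoglobulins, at -0.48, CA3B and LOC422926 at -0.45, C6orf203 at -0.42 and ORAOV1 at -0.41.

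On the positive side, the named genes at or above that median differed less. The cut rests on mean log2 values. POT1 (1201 in H2A.Z.1 cells and 1798 in R80C cells, 1.53-fold higher) and CITED4 (1279 and 660, 1.87-fold lower) therefore lay under it. Among single probes at or above the cut, named or not, more were 2-fold higher than lower in R80C cells. JAK3, a kinase of cytokine receptors, was 1.45-fold higher in R80C cells (signals of 718 and 1018), and TGFB2, a growth factor of the TGF-beta family, was 1.36-fold higher over 3 probes (1125 and 1503). CBY1, an inhibitor of beta-catenin, had a difference of 0.41, NMRAL1 and the adenine salvage gene APRT of 0.39, PDE6G of 0.38, and PPP1R19L and LITAF of 0.36. The tumour suppressor gene NF2 and RAD51D, a gene of DNA repair, stood at 0.35, ATP1B1, a subunit of the sodium pump, at 0.33 over 4 probes, and MARCKSL1 at 0.32.

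Some genes were well above background on 1 array only, and their differences are lower bounds, each for the probe with the largest bound. FABP5, a fatty acid binding protein gene, was at least 52.9-fold higher in R80C cells, where its only probe read 360 against 2.97, not well above background, in H2A.Z.1 cells. MAT1A, a methionine adenosyltransferase gene, was at least 4.21-fold higher in R80C cells, HPGDS, a prostaglandin D synthase gene, at least 3.62-fold and COL20A1, a collagen gene, at least 3.28-fold. The bound for MAT1A rested on 1 of its 3 probes. In the other direction, WWC1, a member of the Hippo pathway, was at least 5.97-fold lower in R80C cells at the probe with the largest bound. All 3 of its probes were above background in H2A.Z.1 cells alone. COL4A1, a basement membrane collagen gene, was at least 4.85-fold lower, P3H2, a collagen prolyl hydroxylase gene, at least 2.63-fold and AHR1A, an aryl hydrocarbon receptor gene, at least 2.26-fold. The bound for COL4A1 rested on 1 of 4 probes and that for P3H2 on 1 of 2. In all, 101 named genes were measured in R80C cells only, 12 of them with a bound of at least 2-fold, and 24 in H2A.Z.1 cells only, 5 of them with such a bound. Under a more lenient detection flag, 135 and 78 genes were measured on 1 array only, and 3 and 1 of them had such a bound. The lowest signal well above background was 5.81 on the R80C array and 6.95 on the H2A.Z.1 array. Some genes measured in R80C cells only had a bound below 0, such as GFI1B, with 8.43 in H2A.Z.1 cells and 7.99 in R80C cells. The counts of genes measured on 1 array only therefore depend on the detection limit of each array. Another 929 named genes had no probe well above background on either array.

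**Figure D2:**
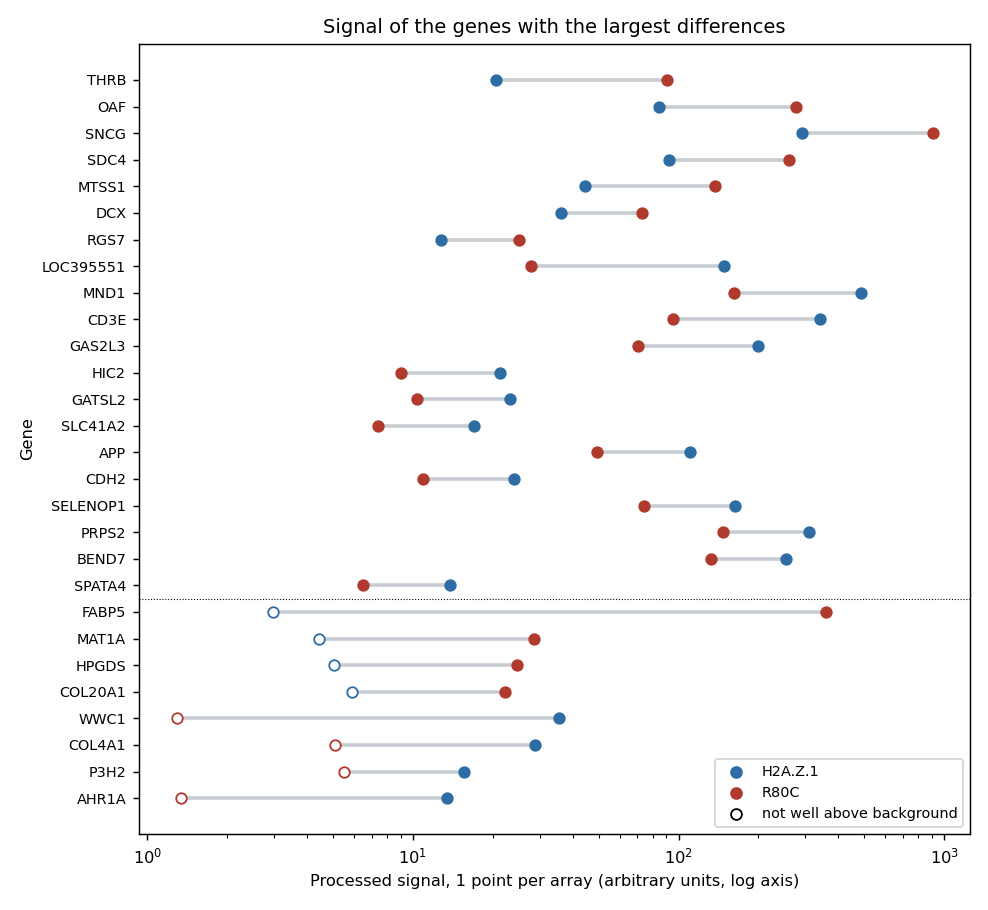
Processed signal (x axis, log scale, arbitrary units) of the 20 genes at least 2-fold different and, under the dotted line, of the 8 genes with the largest lower bounds among those measured on 1 array only, 1 gene per line on the y axis. For these 8 genes the signal is that of the probe with the largest bound. Blue points are the H2A.Z.1 array, red points the R80C array, and open points signals not well above background. FABP5 spans the widest range, from 2.97 to 360.

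The 5 lists on mitosis showed small differences in the genes that could be measured. Of 143 genes on them that the naming table held, 80 were measured on both arrays, none of them 1.5-fold different, with a median of 0.012. In the main scaling 48 lay above 0 and 32 below, and after loess between the arrays 35 lay above and 45 below, so the signs of such small values followed the scaling. The extremes were FOXM1, the transcription factor that drives mitotic genes, 1.18-fold lower in R80C cells over 4 probes, and CENPH, a kinetochore protein gene, 1.14-fold higher over 2 probes. For mitotic entry kinases and cyclins (16 genes), the median of 0.0094 lay at percentile 35.1 among random lists of the same size and signal. ENSA, an inhibitor of a mitotic phosphatase, stood at 0.16 and the kinase gene PLK1 at 0.067. The spindle checkpoint and anaphase-promoting complex list (11 genes) had a median of 0.012 at percentile 38.0, with FZR1 at 0.11 and CDC20 at 0.081, both activators of that complex. The centromere and kinetochore list (21 genes) had a median of 0.029 at percentile 71.5, with CENPH at 0.19 and CENPM at 0.11. The list of spindle, passenger complex and cytokinesis genes (20) had a median of -0.0016 at percentile 13.5, with INCENP at -0.11 and TACC3 at -0.077. Cohesin, condensin and topoisomerase II genes (12) had a median of 0.012 at percentile 41.1, with the condensin subunit gene NCAPH at 0.10 and SMC5 at 0.069.

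The medians of chromatin and genome maintenance lists were likewise close to 0. The complexes that exchange H2A.Z (11 genes) had a median of 0.00011 at percentile 29.1, with ACTR6 at 0.078 and INO80 at 0.065. Histone genes (12) had a median of 0.024 at percentile 66.4, with HIST2H4B at 0.15 and HIST1H2B8 at 0.10. Polycomb, DNA and histone modifiers (28) had a median of 0.038 at percentile 86.5, with the Polycomb gene BMI1 at 0.22 and the DNA demethylase gene TET2 at 0.21. DNA repair genes (33) had a median of 0.011 at percentile 49.1, with RAD51D at 0.35 and FANCD2 at 0.16. DNA replication and G1/S genes (27) had a median of -0.013 at percentile 2.51, with CCNE1 at -0.17 and the primase gene PRIM2 at -0.11, and normexp with quantile normalization moved this list to percentile 0.465. The p53 and damage response targets (9) had a median of 0.080 at percentile 93.6, with GADD45A at 0.29 and CDKN1A at 0.21, while TP53INP1 stood farthest from 0 at -0.47. For apoptosis genes (16) the median was -0.021 at percentile 11.4, with BAK1 at -0.50 and BOK at -0.14, and its place ranged from percentile 1.12 with members matched by exact symbol, chosen after the data were seen, to 63.6 with the median probe of a gene.

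Ribosome biogenesis was the 1 list of 27 whose median lay outside percentiles 1 to 99. All 21 of its measured genes were above 0 in the main scaling and 17 of 21 after loess, with a median of 0.068 at percentile 99.2 and the highest values at WDR3 (0.18) and BRIX1 (0.15), both ribosome assembly factors. No member was 1.5-fold different, and 0.54 of 27 lists would lie outside these percentiles by chance. The list stood at percentile 98.9 after quantile normalization and 98.4 among genes at or above the median signal. Cytosolic ribosomal protein genes (51) had a median of 0.011 at percentile 15.3, with RPS4Y1 at 0.16 and RPL22L1 at 0.14.

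Genes of B cells and of other cell types included the widest values. B cell genes (32) had a median of -0.028 at percentile 2.26, with 21 members below 0 in the main scaling and 15 when arrays were scaled on their medians, a constant shift that left the percentile as it was. Within that list TNFSF13B, the B cell survival factor BAFF, was 1.96-fold lower in R80C cells over 4 probes and JCHAIN 1.40-fold lower. The list lay at percentile 0.76 after normexp with quantile normalization and 0.24 among genes at or above the median signal. T and NK cell markers (10) had a median of -0.023 at percentile 35.0, with CD3E at -1.54 and CD44 at -0.47. With no filter on dim probes that median was -0.24 at percentile 0.35. Myeloid markers (18) had a median of -0.038 at percentile 18.6, with TIMD4 and CSF3R at -0.54. Erythroid and thrombocyte markers (10) had a median of 0.055 at percentile 81.8, with HBBA, a beta-type globin gene, at 0.25, and stood at percentile 99.4 after normexp with quantile normalization. Fibroblast and mesenchymal markers (17) had a median of 0.10 at percentile 96.3, with the collagen gene COL1A2 at 0.94, whose 4 probes ranged from 0.08 to 1.56, and MYL9 at 0.46. With no filter on dim probes that median was -0.087.

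Signalling, stress and metabolic lists all lay within percentiles 1 to 99. Interferon response genes (15) had a median of -0.050 at percentile 19.5, with IRF7 at -0.24 and TAP1 at -0.18. IRF1, a transcription factor of this response, stood farthest from 0 at 0.67 (1 probe) and was the only member 1.5-fold different. The list mean was 0.016, and the sign of the median turned, at 0.0063 after loess and 0.017 after normexp with quantile normalization. NF-kB and cytokine genes (11) had a median of -0.0097 at percentile 32.4, with NFKBIA at -0.16 and CCL20 at -0.14, but a mean of 0.045, with IL21R and LITAF at 0.36. Immediate early genes (14) had a median of -0.031 at percentile 11.0, with NFIL3 at -0.49 and ID3 at -0.47. Heat shock protein genes (20) had a median of 0.050 at percentile 94.7, with HSPA4L at 0.21 and HSPB2 at 0.13. The unfolded protein and integrated stress response list (20) had a median of 0.037 at percentile 77.7, with the amino acid transporter gene SLC7A5 at 0.22 and MTHFD2 at 0.12. Glycolysis and hypoxia genes (31) had a median of 0.043 at percentile 94.6, with LDHA and BHLHE40 at 0.30, while HIF1A, a transcription factor of the hypoxia response, stood farthest from 0 at -0.44, with its 7 probes between -0.52 and -0.25. Oxidative phosphorylation genes (33) had a median of -0.0018 at percentile 3.94, with ATP5S at -0.27 and NDUFV3 at -0.12. Cholesterol and fatty acid synthesis genes (19) had a median of 0.0044 at percentile 23.4, with HSD17B7 at 0.099 and FDFT1 at 0.097. In the main scaling, the member farthest from 0 lay opposite to the median in 11 of the 27 lists, a count that depends on where 0 lies for medians this small. Besides FOXM1, TP53INP1, IRF1, IL21R and HIF1A, such members included NFRKB (-0.11) of the exchange complexes, ANAPC13 (-0.14) of the spindle checkpoint list, PRC1 (0.18) of the spindle list, EPB41 (-0.26) of the erythroid list and HSPB11 (-0.23) of the heat shock list. These opposite members were named after their values were seen. Mean and median had opposite signs in 8 lists in the main scaling, and the median of each of these changed sign under at least 1 other scaling. They were the exchange complexes, mitotic entry, spindle checkpoint, spindle, interferon, NF-kB, oxidative phosphorylation and cholesterol lists.

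**Figure D3:**
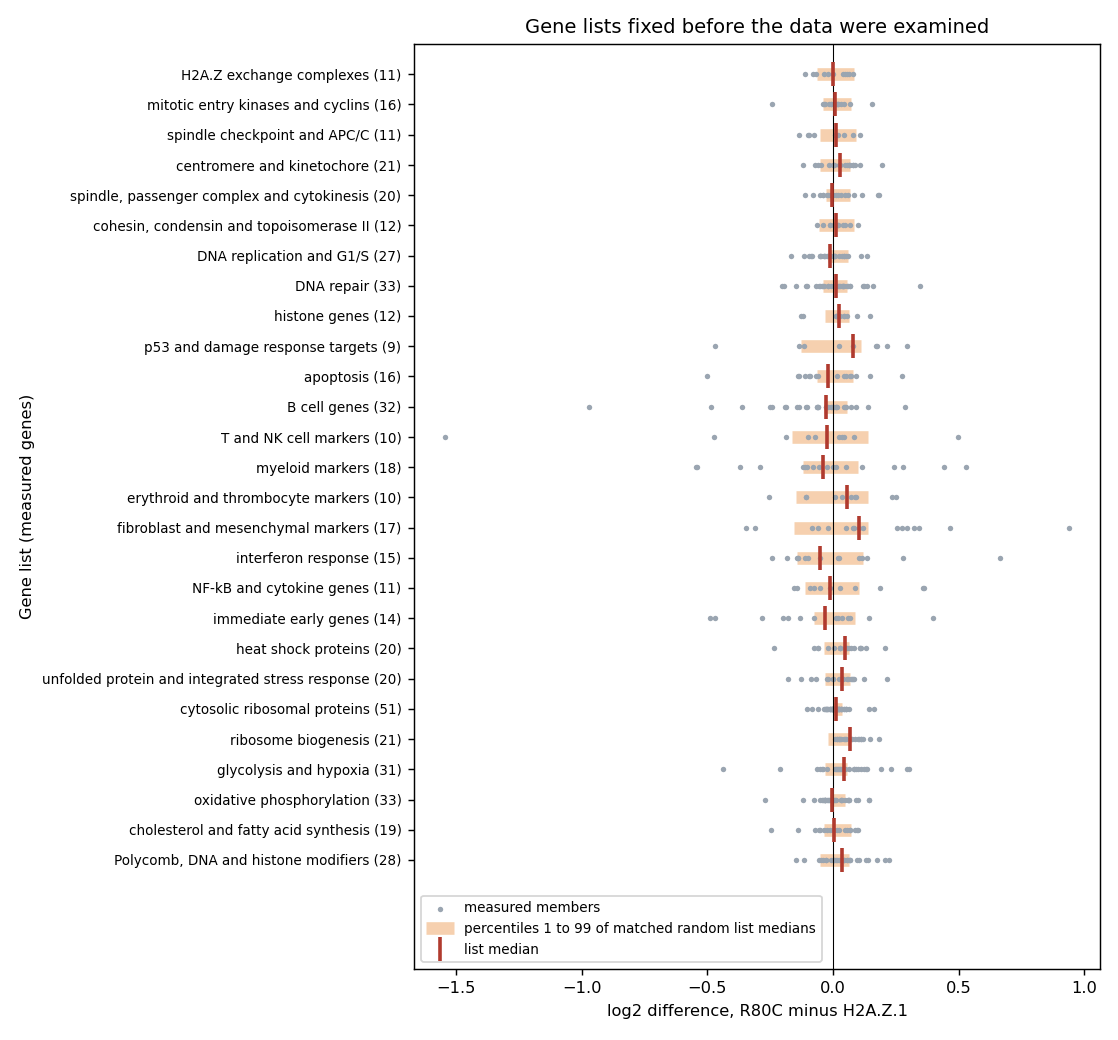
Log2 difference, R80C minus H2A.Z.1 (x axis), of the measured members of each of the 27 gene lists (y axis, number of measured genes in brackets). Grey points are genes, red bars list medians, and orange bands percentiles 1 to 99 of the medians of 10000 random lists matched on signal. Only the ribosome biogenesis median, at 0.068, lies beyond its band, and CD3E at -1.54 is the point farthest from 0.

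Probes without a gene name held further differences. Of all 30200 probes measured on both arrays, 52 were at least 2-fold higher and 90 at least 2-fold lower in R80C cells, and 37 and 62 of these had no gene name here. The largest values among unnamed probes were 2.43 for A_87_P293773 and 2.42 for A_87_P012786, and -3.67 for A_87_P066056 and -3.36 for A_87_P023396. After normexp with quantile normalization, 20 probes were 2-fold higher and 11 lower.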

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

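Matching list members by exact symbol was the 1 alternative chosen after the data were seen. No paired analysis was possible because the groups shared only replicate number 1 and no result came from a test. A value without a test counted as moved when it shifted by more than 0.053 (log2), the SD between repeated spots. The counts of 7 genes higher and 13 lower became 3 and 2 after normexp with quantile normalization, 52 and 45 with no filter on dim probes, and 0 and 0 among genes at or above the median signal, and they stayed within 1.5 times under the 8 other settings. The 52 probes higher and 90 lower became, in the same order, 20 and 11, 759 and 836, and 12 and 4. The normexp setting also replaced the processed by the raw median signal, and no setting separated that from its offset, which shrinks differences of dim spots by construction. The lack of a filter adds signals near background, and the restriction to bright genes removes all 20 genes. Of the 20 genes, 5 (OAF, SNCG, SDC4, LOC395551 and MND1) kept a 2-fold difference after normexp, 14 with no filter, 16 with the brightest probe, and 19 or 20 under the 7 remaining settings that tested them. The bounds of at least 2-fold, 12 in R80C cells and 5 in H2A.Z.1 cells, were 3 and 1 under the lenient detection flag, which counts more dim signals as present. H2AFZ moved to -0.028 with its brightest probe. Of 317 list medians under alternatives, 309 moved by less than that SD, which says little, since most list medians are smaller than it. The others were 0.024 for p53 targets with the brightest probe, -0.24 for T and NK cell markers, -0.087 for fibroblast markers, -0.14 for interferon genes and -0.10 for immediate early genes with no filter, 0.038 for fibroblast markers and 0.017 for interferon genes after normexp, and 0.0063 for interferon genes after loess. The cause of these shifts was not tested. Over the 6 other scalings 17 of the 27 list medians changed sign. Scaling on the array median, the spike-in probes or the series matrix shifts all genes by about a constant and turns signs near 0 by construction, and 9 lists changed sign under quantile normalization, loess or normexp. Of 475 values of the 45 named genes tracked, 422 moved by less than that SD, and H2AFZ was the 1 gene whose sign changed. Signal over background limited the comparison: the difference between the arrays had an SD between probes of a gene of 0.13 in the dimmer part of the genes and 0.047 in the brighter part.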

Other observations

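The tests of spot noise, of chromosome blocks, of clone or culture and of T cells were chosen after the results they bear on had been seen, and the test of signal-dependent bias before. The genes in the next paragraph were chosen after their values were seen.

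Between 1.5-fold and 2-fold lay 64 named genes. Of these, 26 had several measured probes, and in 11 of the 26 every probe was itself at least 1.5-fold different. Probes of a gene picked on their own mean tend to share its direction, so a shared direction is no separate evidence. In R80C cells, ANXA5, an annexin that binds phosphatidylserine, was 1.99-fold lower, VIM, the intermediate filament vimentin, 1.86-fold lower over 3 probes, and CSTB, a cathepsin inhibitor, 1.72-fold lower over 4 probes. The kinase gene DYRK2 was 1.67-fold lower over 3 probes, FRZB, a secreted Wnt antagonist, 1.70-fold lower over 5 probes, PAK1, a kinase that acts on the cytoskeleton, 1.54-fold lower over 4 probes, and the iron exporter gene SLC40A1 1.52-fold lower over 3 probes. POT1, which binds telomeric DNA, was 1.53-fold higher, with its 5 probes between 0.42 and 0.80. FLT1, a VEGF receptor gene, was 1.76-fold higher over 3 probes, FOXD1 1.89-fold higher and CD1C, a lipid antigen presenting molecule, 1.74-fold higher over 2 probes. Probes without a gene name also included some above background on 1 array only, 769 in R80C cells and 264 in H2A.Z.1 cells, of which 31 and 50 had a bound of at least 2-fold.

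The first pattern was the set of probes at least 2-fold different. Of its 142 probes, 62, from 38 transcripts or genes, had another measured probe, and spot noise could be examined for these alone. The other probes of the same transcript or gene had a median difference of 1.04 in the same direction (bootstrap interval 0.94 to 1.17). They pointed the same way for 61 of the 62 and were at least 2-fold different for 37. These values argue against spot noise for the 62, which share transcripts or genes and so are not independent. The remaining probes were not tested. For the 20 named genes, the 5 measured genes on each side argued against gain or loss of a chromosome block spanning most of them. Those neighbours had a median difference of 0.0056 in the direction of the gene (bootstrap interval -0.026 to 0.011), from -0.11 for LOC395551 to 0.17 for MND1. Only 4326 named genes were measured, so a smaller block could lie between these neighbours. Such blocks and changes of single genes, such as an integration site or a small deletion, stay open. Clone or culture and the mutation cannot be told apart with 1 array per group, since a line derived from 1 cell may carry its own expression state.

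The second pattern was CD3E, 2.91-fold lower in R80C cells over 2 probes in a B cell line. T cells in the H2A.Z.1 culture could account for it, but they would bring down other markers of the list as well, where the line itself gives little signal. The 9 other measured T and NK cell markers had a median of 0.026 and ranged from -0.47 to 0.50, far from -1.54. Of 2 further chains of the same receptor complex, CD247 stood at 0.046 over 2 probes. CD3D stood at -0.071 over 2 probes, with signals of 39701 in H2A.Z.1 cells and 36047 in R80C cells. Against signals this high, T cells giving the CD3E difference could leave CD3D nearly unchanged, so CD3D could not decide this. All 9 had to be well above background on both arrays, so markers present in the H2A.Z.1 culture alone were left out. With no filter on dim probes the list shifted to -0.24 at percentile 0.35, the direction that T cells would give, but this came with markers not well above background. The measured markers thus argue against T cells only for genes detected on both arrays. A difference in CD3E itself between the lines stays open as a hypothesis.

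The third pattern was the small difference of ribosome biogenesis genes, with all 21 above 0 and a median of 0.068 in the main scaling. A signal-dependent bias between the arrays could give such a shift. The random lists were matched on signal, which already takes most of such a trend out of the percentile in the main scaling (99.2). The percentile of 99.2 after loess, which removes such a trend, therefore could not decide this. After loess the median was 0.051, with 17 of 21 genes above 0. Quantile normalization left the list at percentile 98.9, under the limit. Chance stays open, since 0.54 of 27 lists would lie outside percentiles 1 to 99, and a difference in growth between 2 cultures, with or without the mutation as its source, was not tested.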
